A study of Mus musculus with 2 samples.

How the data were processed

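Colon epithelial cells of C57BL/6 mice aged 7 weeks were incubated with PBS or with MIF, and 1 array was made of each. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was prepared by the standard Affymetrix protocol. The dose and time of incubation, the number of animals and how the epithelial cells were isolated are not given in the sources used here. The deposited values are the authors' processed signal intensity of each probe set, on a linear scale, which was read from the values themselves. The method of summarising probes, the background correction and the scaling between arrays are not given in the sources used here, nor is how the 15340 probe sets of the table were chosen. Of these, 61 are array controls and were left out.

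Probe sets were named through the platform annotation of GEO, which can be old. Of the 15279 other probe sets, 14049 had 1 gene symbol, 490 had several and 740 had none. Those with several or none were left unnamed. Symbols were updated through the Entrez ID for 14034 probe sets, using the gene table of the mouse assembly GRCm38.p6 for names only. No coordinates are given, since the annotation used here carries no genome build.

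The medians of the columns differed by 0.04 on the log2 scale, less than the limit of 0.1 for centring, so the columns were used as deposited. A floor was set at the 40th percentile of all signals of both arrays, a signal of 232, and lower values were raised to it. A gene was represented by its probe set with the highest mean log2 signal. A gene under the floor on both arrays was not assessed (2884 genes). With a single array under the floor (150 genes on the PBS array and 142 on the MIF array), the difference is a lower bound, written as at least N-fold. Differences are log2 signal on the MIF array minus the PBS array. With 1 array per group there is no residual error, so no p-value, SD between samples or test is given, and the number of arrays limits the precision.

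In all, 39 gene lists with 753 genes were fixed before the data were examined, covering MIF and its receptors, signalling, antigen presentation, cell cycle, survival, epithelial cell types, other cell types, stress and metabolism. The table held 541 of these genes. The median log2 difference of each list with at least 5 assessed genes was placed as a percentile among 10000 random lists of equal size, matched on mean expression in 20 bins. A list was said to stand apart at or below the 2.5th or at or above the 97.5th percentile. By chance 5% of lists would do so if their genes varied independently. These percentiles describe these arrays and are not p-values. Named genes followed a rule fixed at the same time. It took the 12 largest differences in each direction among genes above the floor on both arrays with no opposed probe set. It added the 3 largest bounds in each direction, every assessed gene of the MIF list, and 2 to 4 members with the largest differences in each other list, leaving out predicted genes. Ctss, H2-K1, H2-D1, B2m, Erap1, Zg16, Fcgbp, Tff3, Nadk, Svs5 and the genes named only in the closing section are outside this rule and were chosen after their values were seen.

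The alternatives were the columns as deposited, median centring, quantile normalization, a floor at the 20th or 60th percentile, no floor, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, removing a loess trend of the difference with intensity (span 0.3), and thresholds of 1.5-fold and 3-fold. Their effect on a list was read from whether it still stood apart. A named gene was called moved where its difference shifted by more than the SD between probe sets of a gene, 0.13 on the log2 scale, and a count where it changed by more than 1.5 times.

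Over 4 nearly equal groups of probe sets above the floor, from the lowest to the highest mean signal, the median log2 difference was 0.03, 0.02, -0.0026 and -0.05. The ratio of 3' to 5' control signals was 1.31 and 1.33 for beta-actin, 0.798 and 0.796 for Gapdh, and 2.34 and 2.23 for the transferrin receptor on the PBS and MIF arrays. The 9 bacterial and phage hybridisation controls had a median log2 difference of 0.05, from -0.08 to 0.16.

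The steps were tested on simulated data with 5830 genes. All 200 genes planted with a log2 difference of 1.5 were counted and no other gene was. The planted genes lay well above the floor on both arrays and the planted difference exceeded the 2-fold threshold. This count therefore shows nothing of genes near the floor. The simulated noise was independent between probe sets, unlike genes that vary together. Of 100 lists of 15 genes with no shift, 6 stood apart. Of 50 lists shifted by 0.15, 43 did, and of 50 shifted by 0.3, all 50 did. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.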

Results

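Gene expression was measured in colon epithelial cells of C57BL/6 mice, an inbred laboratory strain, aged 7 weeks. The cells had been incubated either with PBS, a buffered salt solution, or with MIF, taken here to be macrophage migration inhibitory factor, a cytokine that binds the cell surface protein CD74. RNA of each incubation was hybridised to 1 Affymetrix array, so the comparison has no replicates and no test against a spread between samples was possible. The table held 15340 probe sets. The median signal of all probe sets, controls included, was 337 on the PBS array and 346 on the MIF array, a log2 difference of 0.04. Signals ran from 0.402 to 15440 on the PBS array and from 0.615 to 15364 on the MIF array. Of 8721 named genes, 5545 lay above the signal floor of 232 on both arrays, 150 lay under it on the PBS array alone and 142 on the MIF array alone.

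The comparison asked which transcripts differed between cells incubated with MIF and cells incubated with PBS. Genes of antigen presentation were lower in the MIF-incubated array, led by the major histocompatibility complex (MHC) class II genes H2-Ab1 and H2-Eb1, at 1.95-fold and 1.94-fold lower. Genes of mitosis were lower by a smaller amount, with a median log2 difference of -0.29. Immediate early genes and goblet cell markers were higher, with medians of 0.18 and 0.13. The fibroblast gene Dcn was 2.89-fold higher, from a PBS signal near the floor, and the cytotoxic granule genes Gzma and Gzmb were 2.02-fold and 1.92-fold lower.

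Most genes had nearly equal signals on both arrays. Over the probe sets above the floor on both arrays, the log2 signals had a Pearson r of 0.990 across probe sets, which are not independent replicates. Of 5837 assessed genes, 5773 (98.9%) lay within 1.5-fold, with genes under the floor on 1 array (150 for PBS and 142 for MIF) counted at their bound. The full difference of such a gene may be larger. The SD of the log2 difference over genes above the floor on both arrays was 0.19. At 2-fold, 4 genes were higher and 5 lower in the MIF-incubated array. At 1.5-fold these counts were 37 and 27. The 2-fold counts depended on the floor, being 14 and 9 with it at the 20th percentile, 1 and 1 at the 60th, and 170 and 79 with none.

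Among genes above the floor on both arrays, Dcn, which encodes the collagen-binding proteoglycan decorin, had the largest difference towards MIF, from 235 to 678. Its PBS signal lay just above the floor, and with the floor at the 60th percentile its log2 difference was a bound of 0.45. Erdr1, a gene of the pseudoautosomal region, went from a signal of 675 on the PBS array to 1567 on the MIF array (2.32-fold), measured by a probe set that can cross-hybridise. Sval1 was 2.00-fold higher at 4650, just under the 2-fold threshold before rounding. Pck1, the cytosolic enzyme that commits oxaloacetate to gluconeogenesis, was 1.85-fold higher, and the C-type lectin gene Clec2h was 1.80-fold higher. Clcn5, a chloride and proton exchanger, and Ramp1, a subunit of the receptor for the neuropeptide CGRP, were 1.79-fold and 1.74-fold higher. The Clcn5 probe set can cross-hybridise, and a second one was at least 1.10-fold higher. The sialyltransferase gene St3gal6 and the ubiquitin-associated gene Ubap2 were both 1.70-fold higher. The chemokine gene Ccl6 was 1.69-fold higher, the folate hydrolase gene Ggh 1.65-fold and the transglutaminase gene Tgm3 1.63-fold. Where the PBS signal lay under the floor, Col3a1, a fibrillar collagen, was at least 2.39-fold higher. Ccn3, a secreted matricellular protein, was at least 2.15-fold higher, from a probe set that can cross-hybridise, and Timmdc1, an assembly factor of respiratory complex I, at least 1.77-fold.

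In the other direction, Upp1, the uridine phosphorylase of pyrimidine salvage, was 2.23-fold lower in the MIF-incubated array, from 3590 to 1608. Rps6, a ribosomal protein gene, was 2.01-fold lower on its single probe set, at signals of 529 and 263 near the floor. Iigp1, an interferon-inducible GTPase that acts against intracellular pathogens, was 1.99-fold lower, from 1739 to 874. S100g, a vitamin D-regulated calcium-binding protein, was 1.92-fold lower, as was the O-glucosyltransferase gene Poglut2, whose MIF signal of 238 was near the floor. Tbc1d13, of a family of Rab GTPase-activating proteins, was 1.81-fold lower and the lysosomal peptidase gene Dpp7 1.75-fold. Where the MIF signal lay under the floor, the sialyltransferase gene St6galnac4 was at least 3.08-fold lower, with a PBS signal of 713. Svs4, a seminal vesicle secretory protein gene, was at least 2.09-fold lower, with a PBS signal of 484, and the brightest probe set of Svs5, of the same secretion, was at 257 on the PBS array and 3.14 on the MIF array. Ido1, a tryptophan-degrading enzyme induced by interferon gamma, was at least 1.82-fold lower, with a PBS signal of 422.

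**Figure D1:**
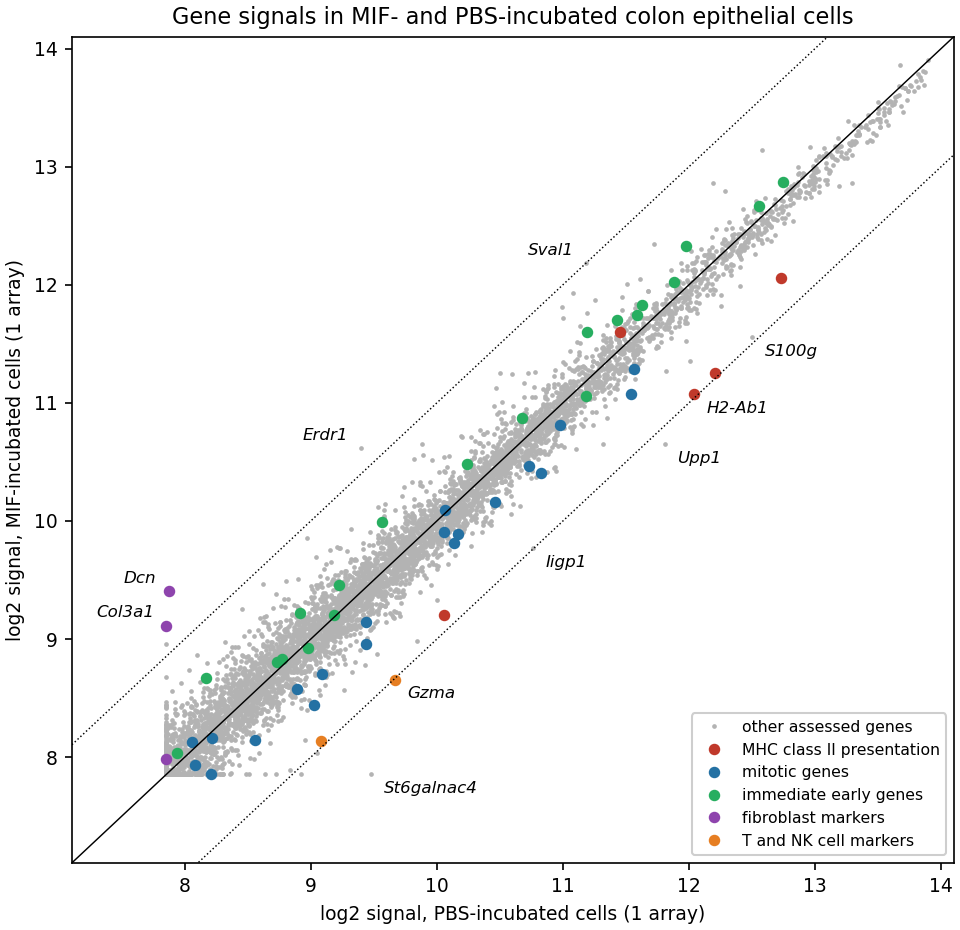
The log2 signal of each assessed gene on the PBS array (x axis) and the MIF array (y axis), 1 array each, with signals under the floor raised to it; the solid line marks equal signals and the dotted lines a 2-fold difference. Most of the 5837 genes lie close to the solid line, with Dcn 2.89-fold higher, from a PBS signal near the floor, and Upp1 2.23-fold lower in the MIF-incubated array.

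The genes of MIF itself and of its receptors were first examined. Cd74, the invariant chain of MHC class II and the surface receptor of MIF, was 1.35-fold lower in the MIF-incubated array, from 10033 to 7423. Mif had nearly equal signals, at 2452 and 2433. Its homologue Ddt was 1.12-fold lower, and Cd44, which signals together with CD74, had a log2 difference of 0.04. With 4 assessed genes, this list was not set against random lists.

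Of the 39 gene lists, 28 had at least 5 assessed genes and were set against 10000 random lists matched on expression. Of these, 5 stood apart on the higher side and 3 on the lower side. About 1.4 in all would do so by chance if the genes of a list varied independently. Genes of a list may vary together and some lists share members, so this does not measure chance between samples.

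**Figure D2:**
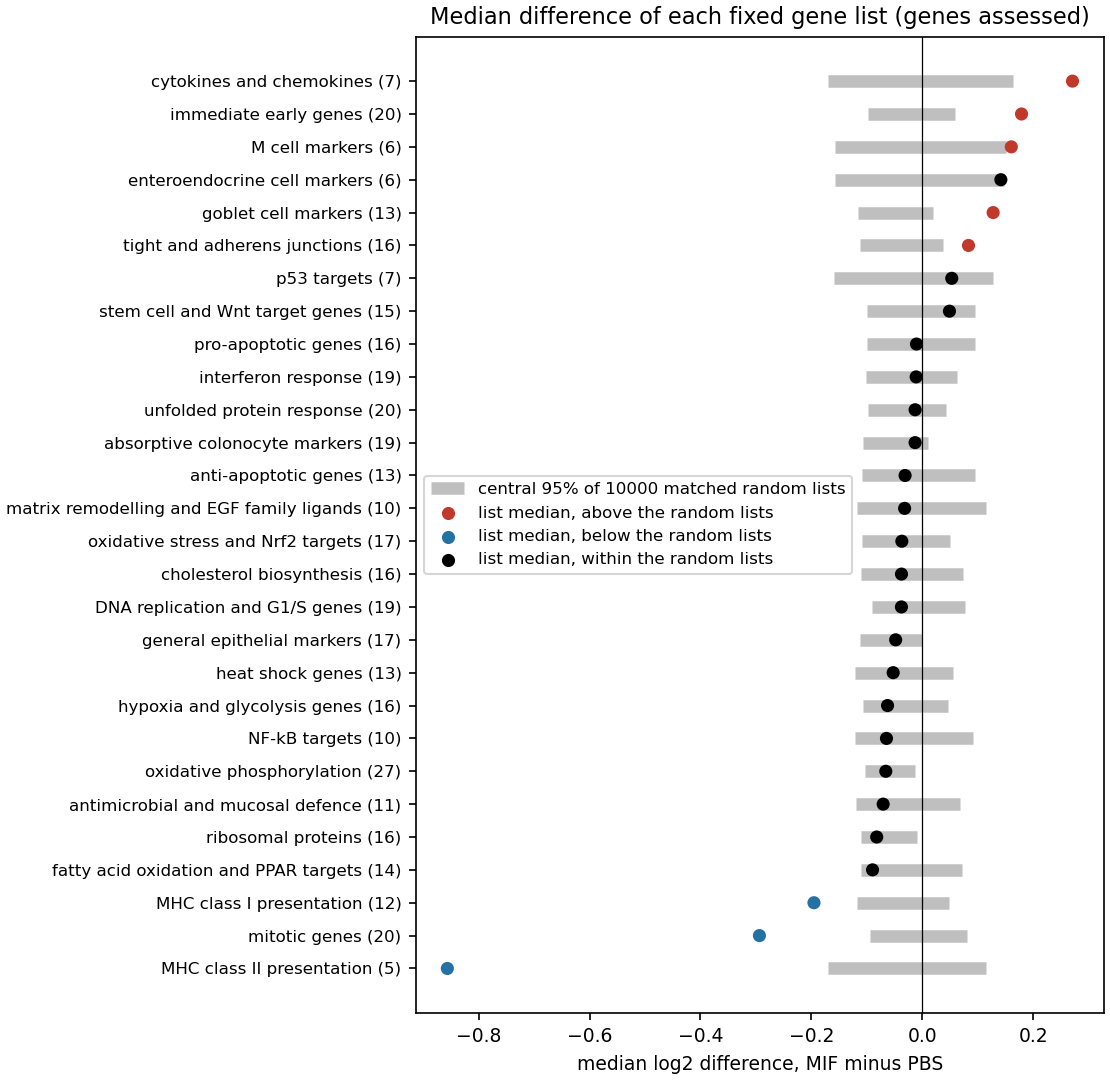
Median log2 difference, MIF minus PBS, of the 28 gene lists with at least 5 assessed genes (points; number of assessed genes in brackets) over the central 95% of 10000 expression-matched random lists (grey bars). The list furthest below its random lists is MHC class II presentation at -0.86, and the list furthest above 0 is cytokines and chemokines at 0.27.

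MHC class II genes, whose products present extracellular peptides to helper T cells, had a median log2 difference of -0.86, below all 10000 random lists. Of 5 assessed members, 4 were at least 1.5-fold lower. These were H2-Ab1 (4213 on the PBS array and 2157 on the MIF array), H2-Eb1, H2-DMa, which loads peptides and was 1.81-fold lower, and H2-Aa, which was 1.59-fold lower. The protease gene Ctss, the remaining member, was 1.11-fold higher. The MHC class I presentation list had a median of -0.20, also below all random lists, and 11 of its 12 assessed members were lower. The largest differences were in the immunoproteasome subunits Psmb9 (-0.66), Psmb8 (-0.45) and Psmb10 (-0.31) and in the peptide transporter Tap1 (-0.30). The MHC class I genes H2-K1, H2-D1 and B2m differed less, by -0.18, -0.08 and -0.06, and Erap1 was the member not lower, at 0.02. Among T and NK cell markers, the granule proteases were lower, Gzma at 813 on the PBS array and 403 on the MIF array and Gzmb at 541 and 282. They were the 2 assessed markers of that list, whose other 5 genes in the table lay under the floor on both arrays.

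The interferon response list, which shares Psmb8 and Psmb9 with the class I list, did not stand apart. Its median was -0.01, at percentile 54.4 of random lists, with 8 of 19 assessed members higher and 11 lower. Iigp1 (-0.99) was the lowest member, whereas Rsad2, an antiviral enzyme induced by type I interferon, was higher at 0.52.

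Mitotic genes had a median of -0.29, below all random lists, with 18 of 20 assessed members lower. Prc1, a spindle midzone protein, differed by -0.59, the centromeric histone gene Cenpa by -0.48, Cdc20, an activator of the anaphase-promoting complex, by -0.46, and Ube2c, a ubiquitin-conjugating enzyme of that complex, by -0.42. Genes of DNA replication and entry into S phase did not stand apart. Their median was -0.04, at percentile 24.9, although Tk1, Mcm6 and Lig1 had differences of -0.37, -0.34 and -0.34. With averaged probe sets the median was -0.0919, at percentile 0.785, and the list stood apart.

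Immediate early genes, which are transcribed within minutes of many stimuli, had a median of 0.18, above all random lists. Of 20 assessed members, 18 were higher and none reached 1.5-fold. Fosb was 1.41-fold higher, Atf3 1.34-fold, Zfp36, which destabilises cytokine transcripts, 1.33-fold and Jun 1.28-fold. Cytokine and chemokine genes had a median of 0.27, at percentile 99.9, with 6 of 7 assessed members higher. Ccl6 (0.75), the interleukin 1 antagonist Il1rn (0.35) and the mucosal chemokine Ccl28 (0.30) were higher, and Cxcl9, an interferon gamma-induced chemokine, was lower at -0.44, with a MIF signal of 233 near the floor. This list no longer stood apart with the floor at the 20th percentile of signals, where its median was 0.11. Targets of NF-kB, the transcription factor of inflammatory signalling, had a median of -0.06 at percentile 20.8, and 9 of 10 assessed members were lower. The largest differences among them were in Tnip1 (-0.54), an inhibitor of that pathway, and the acute phase gene Saa3 (-0.45).

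Goblet cell markers had a median of 0.13, above 99.99% of random lists, with 11 of 13 assessed members higher. Klk1, a tissue kallikrein, was higher by 0.57, the transcription factor genes Creb3l1 and Spdef by 0.55 and 0.44, and Clca1, a secreted mucus protein, by 0.51. The abundant mucus proteins Zg16 and Fcgbp and the trefoil factor Tff3 differed by 0.01, 0.02 and -0.01. Tight and adherens junction genes had a median of 0.08 at percentile 99.9, with 10 of 16 members higher, among them the claudin Cldn8 (0.65) and the catenin Ctnnd1 (0.48). M cell markers, of the cells that carry antigens across the epithelium, had a median of 0.16 at percentile 98.0 over 6 members, including Tnfrsf11a (0.41) and Marcksl1 (0.40, from 235 near the floor). The M cell list was within the random range without a floor, with averaged probe sets and without cross-hybridising probe sets.

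With the floor and scaling used here, other epithelial lists did not stand apart. Enteroendocrine markers had a median of 0.14 at percentile 97.0, with the hormone gene Sct, for secretin, at -0.67 and the granin gene Chgb at 0.43. The enteroendocrine list stood apart with the floor at the 20th percentile (0.23), with no floor (0.28) and with averaged probe sets (0.14). Absorptive colonocyte markers had a median of -0.01 at percentile 88.9, with the water channel Aqp4 at 0.62, Ms4a10 at -0.48 and the bile acid transporter subunit Slc51a at -0.43. This median was above 0 after quantile normalization or removal of the trend with intensity, at 0.06 and 0.05, and stood apart there. Stem cell and Wnt target genes had a median of 0.05 at percentile 85.8, with Smoc2 at 0.37 and Ephb3 at 0.36, the latter from 238 near the floor. Without a floor the median of this list was 0.11, at percentile 97.8, and it stood apart. General epithelial markers, such as the keratin Krt19 (-0.23) and the cadherin Cdh1 (0.21), had a median of -0.05 at percentile 65.3, which turned to 0.0012 with quantile normalization. The only tuft cell marker assessed, Cd24a, was higher by 0.26.

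**Figure D3:**
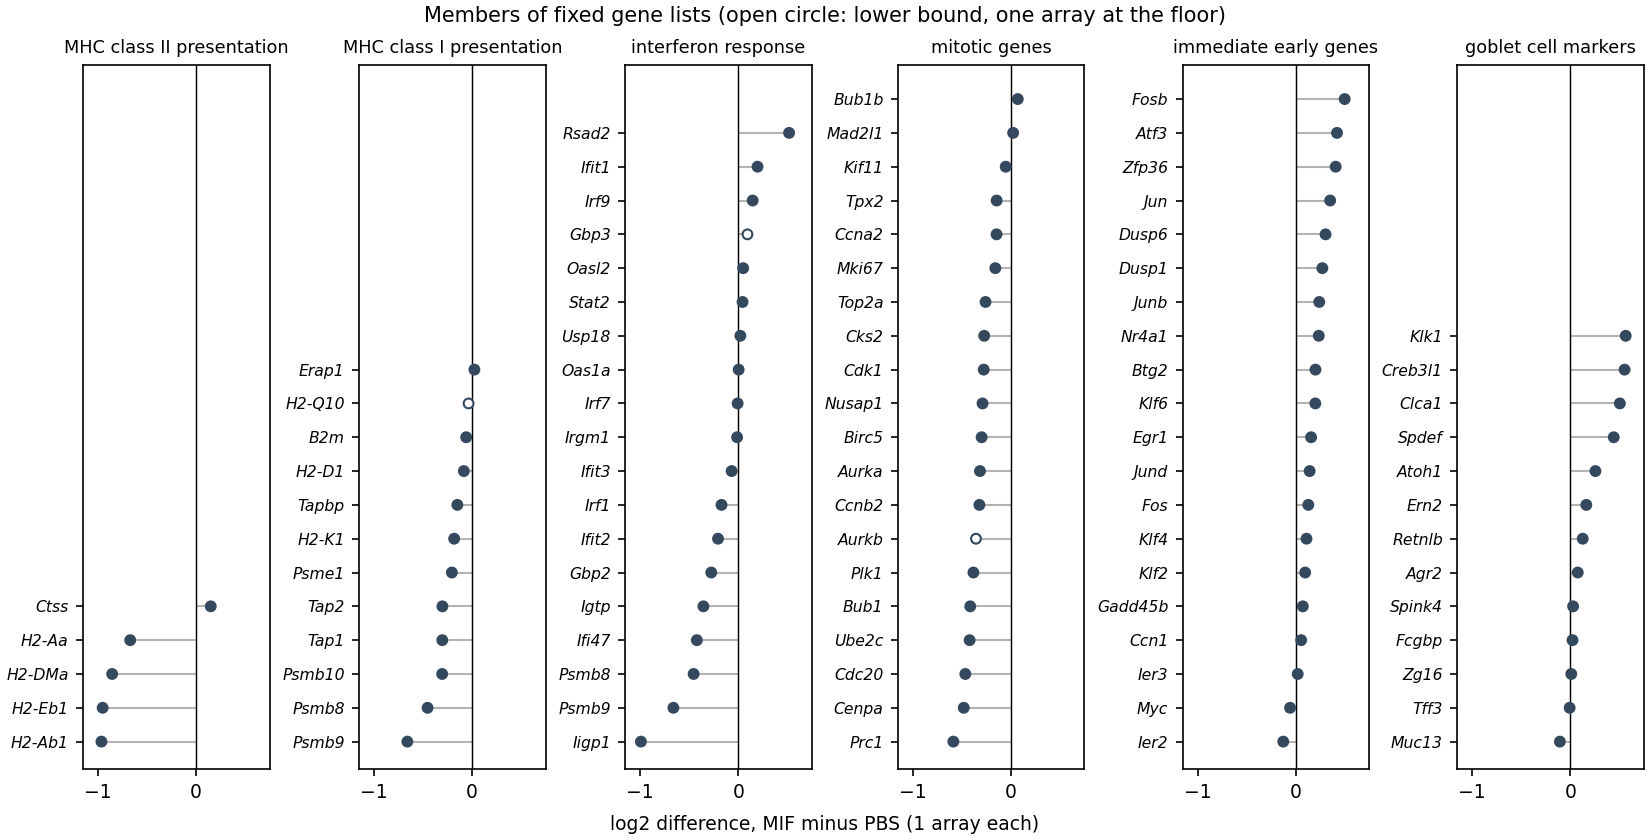
Log2 difference, MIF minus PBS, of each assessed member of 6 gene lists, from 1 array each; open circles are lower bounds with a single array under the floor. In the mitotic list 18 of 20 members lie below 0, and in the immediate early list 18 of 20 lie above 0.

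Lists of survival and stress genes had small medians, within the random range. Anti-apoptotic genes had a median of -0.03 (percentile 30.6), with Birc5 at -0.30 and Bag1 at -0.23. Pro-apoptotic genes had a median of -0.01 (percentile 44.5), with the mitochondrial protease Htra2 at -0.50 and the BH3-only gene Pmaip1 at 0.50. Targets of p53 had a median of 0.05 (percentile 84.3), with the cell cycle inhibitor Cdkn1a at -0.27 (0.14 on a second probe set) and Btg2 at 0.20. The unfolded protein response list had a median of -0.01 (percentile 65.7), with Creld2 at -0.46 and the chaperone Dnajb9 at 0.35. Heat shock genes had a median of -0.05 (percentile 35.2), with Hsph1 at -0.39 and Hspa4l at 0.26 (-0.01 on a second probe set). Oxidative stress and Nrf2 targets had a median of -0.04 (percentile 48.2), with catalase, Cat, at -0.31 (0.15 on a second probe set) and Gstm1 at 0.26.

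Metabolic and defence lists were also within the random range. Hypoxia and glycolysis genes had a median of -0.06 (percentile 23.9), with Pdk1 at 0.38 and the oxygen sensor Egln3 at -0.34. Oxidative phosphorylation genes had a median of -0.07 (percentile 44.7), with Ndufv1 at -0.25 and Atp5o at -0.24 (0.10 on a second probe set). Ribosomal protein genes had a median of -0.08 (percentile 23.8), and 15 of 16 lay within 1.5-fold, Rps6 being the exception; Rpsa was next at -0.23. Fatty acid oxidation genes and PPAR targets had a median of -0.09 (percentile 6.92), with the thiolase Acaa1a at -0.51 and the carnitine carrier Slc25a20 at -0.26. Cholesterol biosynthesis genes had a median of -0.04 (percentile 36.1), with Pmvk at -0.23 and Dhcr7 at 0.22. Matrix remodelling genes and ligands of the EGF family had a median of -0.03 (percentile 33.1), with the laminin chain Lamb3 at 0.51 and the integrin Itgb4 at -0.19. Antimicrobial and mucosal defence genes had a median of -0.07 (percentile 25.1), with the lysozyme Lyz1 at 0.53 and the phospholipase Pla2g2a at -0.24.

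Many listed markers of cells other than epithelium were not in the table. It held 7 of 20 T and NK cell, 4 of 19 B and plasma cell and 2 of 16 neuron and glia markers, against 16 of 18 fibroblast markers. Those in the table were mostly under the floor. For lists with few markers in the table, this says little about whether the cells were present. Of the fibroblast markers, Dcn, Col3a1 and Vim were assessed, with a median of 1.26, which is the bound of Col3a1, and Vim was at least 1.09-fold higher. Col3a1 and Vim lay under the floor on the PBS array alone, so their differences could only be positive. The other 13 fibroblast genes in the table lay under the floor on both arrays and were not assessed. Of the myeloid markers, Cd14 differed by -0.01 and Lyz2 was at least 1.05-fold higher. The mast cell markers Kit and Mcpt2 gave bounds of 0.14 and -0.10, and the only smooth muscle gene assessed, the kinase Mylk, differed by -0.20. No B and plasma cell, endothelial, enteric neuron and glia, or erythroid marker in the table was above the floor on either array.

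Separate probe sets of a gene gave a measure of error within these arrays. Of 1800 genes with a second probe set above the floor on both arrays, none had a first probe set at 2-fold. At 1.5-fold, a threshold chosen after the data were seen, the second probe set went in the same direction for 13 of 14 genes, the exception being Nadk with 0.82 and -0.14. The median ratio of the second to the first log2 difference was 0.881, and where the first probe set was within 1.2-fold, 62.2% of genes had the same direction. Such agreement measures the hybridisation of the same RNA, and says nothing of the spread between cell preparations.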

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

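All tests of an explanation in this part were chosen only after the pattern had been seen. A probe set outside the named genes, which the annotation ties to 2 kallikrein genes and which therefore has no single name here, was 2.42-fold higher in the MIF-incubated array, at 381 and 921.

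MHC class II genes were lower in the MIF-incubated array, together with Cd74, Iigp1, Ido1 and the granzyme genes. A trend of the difference with intensity is argued against by its size. The fitted trend reached 0.0935 at most, whereas the median of the MHC class II list was -0.86 after its removal. The list stayed below all random lists, which adds nothing here, since these were matched on expression and share the trend. Fewer antigen-presenting leukocytes in the MIF-incubated sample could not be assessed with the floor in place, because 2 of the 16 myeloid and B cell markers in the table were above it. Without a floor, where dim signals decide little, the 12 myeloid markers had a median of 0.17 at percentile 78.8, 6 higher and 6 lower. The 4 B and plasma cell markers had a median of -0.29, 1 higher and 3 lower, and the MHC class II list one of -0.79. A weaker interferon gamma response in the MIF-incubated sample may account for the pattern. A further list of 28 interferon gamma-induced genes outside the fixed lists had a median of -0.24 over 16 assessed genes, below all random lists. Of these, 15 were lower and Ifi35 was higher at 0.57. The interferon response list fixed beforehand did not stand apart, with a median of -0.01 at percentile 54.4. It was not split by type of interferon, and its members went both ways, 11 lower and 8 higher. The lowest were Iigp1 (-0.99), Psmb9 (-0.66), Psmb8 (-0.45) and Ifi47 (-0.42), and the highest was Rsad2 (0.52). Its median therefore cannot decide on a response to interferon gamma alone. Whether MIF itself, fewer interferon-producing lymphocytes or a difference between the cell preparations led to the lower signals stays open, with 1 array per group.

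The 3 assessed fibroblast genes were higher in the MIF-incubated array, with Dcn at 235 and 678, Col3a1 at 227 and 554 and a small bound for Vim. Col3a1 and Vim lay under the floor on the PBS array and were assessed only through their MIF signal. Their shared direction was therefore fixed by the floor and adds nothing to Dcn. The trend with intensity is argued against, as the median of the 3 genes was 1.22 after the loess correction and the fitted trend reached 0.0935 at most. Stromal cells carried over into the MIF-incubated sample could not be assessed with the floor in place, because 0 of 19 further stromal genes in the table were above it. Without a floor, where dim signals decide little, 18 of the 19, and all 16 genes of the fixed fibroblast list, had the higher signal on the MIF array, as did 58.8% of the 2884 genes under the floor on both arrays. The median of the fixed list was then 1.28, above all random lists, with 13 of the 16 genes at least 2-fold higher. An induction of these genes by MIF was not tested and stays open as well.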

How the results depend on the processing

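The thresholds, floors and scalings were fixed before the data were examined, and the 1.5-fold threshold for paired probe sets was chosen after the data were seen. No paired analysis was possible because each group has 1 array, and no array could be left out. The columns as deposited equal the values used here and centring subtracts about 0, so these 2 settings test nothing. MHC class I, mitotic, immediate early, goblet cell and junction genes, 5 lists, stood apart under every setting. No named gene at 1.5-fold or more with a value under a setting reversed its direction there; Acaa2 turned from -0.15 to 0.0033 without _x_at and _s_at probe sets and Mif from -0.01 to 0.01 with the loess correction. At the 60th percentile floor or without _x_at and _s_at probe sets some named genes had no value. With averaged probe sets 23 moved, with the 60th percentile floor 14, with the 20th percentile floor 8 and with no floor 8. Without _x_at and _s_at probe sets 3 moved, and none did with quantile normalization or the loess correction. For 8 lists with medians within 0.05 of 0 the sign changed under these last settings (colonocyte, general epithelial and mast cell markers, interferon response, pro-apoptotic, unfolded protein response, Nrf2 and cholesterol genes).

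Counts of genes at 2-fold depended on the floor. With the floor at the 20th percentile, 14 genes were higher and 9 lower; at the 60th percentile, 1 and 1; with no floor, where dim signals give large ratios, 170 and 79. Averaged probe sets, or leaving out _x_at and _s_at probe sets, gave 2 higher. At 1.5-fold the counts were 37 and 27, and at 3-fold 0 and 1. The second probe set agreed for 2 of 2 genes with the 20th percentile floor, 21 of 26 with no floor and 13 of 14 at 1.5-fold.

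Among lists that stood apart, cytokines and chemokines had medians of 0.11 (20th percentile floor) and 0.30 (60th, under 5 genes assessed) and no longer did. M cell markers were at 0.0835 (60th, under 5 genes), 0.15 (no floor), 0.0931 (averaged probe sets) and 0.12 (without _x_at and _s_at). MHC class II was at -0.90 without _x_at and _s_at, with too few genes to rank. Other lists stood apart only under some settings. Colonocyte markers did so at 0.0565 (quantile), 0.0014 (60th) and 0.0547 (loess), and enteroendocrine markers at 0.23 (20th), 0.28 (no floor) and 0.14 (averaged). DNA replication did so at -0.0919 (averaged) and fibroblast markers at 1.02 (20th). With no floor, fibroblast markers were at 1.28, stem cell and Wnt targets at 0.11, T and NK markers at -0.61 and smooth muscle at 0.50, all apart. Markers with no gene above the floor had medians there of 0.71 (endothelial, within the random range), 0.39 (neuron and glia), -0.29 (B and plasma cell) and -1.59 (erythroid), the last 3 from under 5 genes. Except where too few genes were left, the cause was not tested. Lists of markers of cells other than epithelium had at most 3 assessed genes, and their other genes in the table lay under the floor on both arrays.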

Other observations

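Of a list of 18 genes of the male accessory glands, made after the values were seen, 4 were in the table. Svs4 had signals of 484 on the PBS array and 3.99 on the MIF array, and the brightest of the 5 probe sets of Svs5 had 257 and 3.14. The other probe sets of these 4 genes lay under the floor on both arrays and were not assessed. At those dim levels each of them also had the higher signal on the PBS array, with Pate4 at 86.7 and 16.6 and Pbsn at 85.6 and 6.19. No explanation for these signals was tested.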
